A study of Mus musculus with 12 samples.

How the data were processed

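Total RNA from the livers of 12 mice was purified with TRIZOL and a spin column, labelled with biotin and hybridised to 1-colour Affymetrix mouse arrays, per the labels' protocols. The deposited values are intensities, 1 linear probe set signal per array, given to 1 decimal. The submitters' processing notes name RMA. The deposited intensities do not look like RMA output, which is on the log2 scale and equal in distribution between arrays. They are linear, reach from 0 to 37251.7, and have the same trimmed mean on all arrays (150.07 to 150.08 with 2% removed from each end) but medians from 38.8 to 47.2, as signals scaled array by array have. The software behind the values is not given in the sources used here, and neither detection calls nor scanner files were used here. Because signals near 0 are part of such a scale, differences between dim probe sets are less certain on the log2 scale, and 28.4% of all values lay below 16.

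The table held 22690 probe sets, of which 64 are control probe sets of the array and were left out of the tests. Gene names came from the platform annotation supplied with the data, with symbols looked up by gene identifier in RefSeq (mouse assembly GRCm38.p6, used for names only). No symbol changed in that step. Of the 22626 tested probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none in the annotation used; the last 2 kinds were counted but not named as genes. Signals were converted to log2 after 1 value of 0 had been set to 0.1. No filter on dim probe sets and no further normalization was applied for the values reported.

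Groups came from the sample titles. A model with 1 mean per group was fitted to all 12 arrays with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, tests of both directions), and 5 contrasts were taken from it: Z on minus Z off, M on minus M off, the difference between those 2, Z on minus M on, and Z off minus M off. P-values were adjusted by Benjamini and Hochberg over the 22626 probe sets, and a call is an adjusted p under 0.05. Gene lists were tested with limma's camera (preset inter-gene correlation 0.01) on 1 probe set per gene, the one with the highest mean, with adjustment over the 35 lists (23 of pathways and gene families, 12 of cell type markers) within a contrast. Of 584 list entries, 505 had a probe set. Camera with an estimated correlation and fry were run beside it. With an estimated correlation no list passed in any contrast. In Z on against Z off the estimate was 0.36 for cholesterol synthesis and 0.25 for ER chaperones, but 0.01 for the integrated stress response. Where the estimate lies above the preset, the p-values with the preset can be too small. Fry, which asks whether the genes of a list move on balance to one side without comparing them with other genes, called only the male-biased list in Z on against M on (adjusted p = 0.0371). Fry's mixed test, which asks whether members change in either direction, also makes no comparison with other genes. It called 13 lists in Z on against Z off. Counts "adjusted over the list alone" use Benjamini and Hochberg over the members of that list.

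The tests, lists, named genes and most alternatives were fixed before the data were examined. Named genes were, per contrast, the called genes with non-overlapping groups (up to 10 in each direction, largest change first, by the called probe set with the highest mean), and where fewer than 5 in a direction passed, those of the smallest unadjusted p up to 5, which are given as values. Up to 4 members of each list with the smallest p, and a fixed set of stress, growth and serpin genes (Rgs16, Hspa5, Ddit3, Xbp1, Nfkbia, Sqstm1, Map1lc3b, Bcap31, Tgfb1, Ccnd1, Alb and the mouse Serpina1 genes), completed the rule. Genes named beyond it were singled out after their values were seen: the unnamed probe sets that were called, Saa1, Saa2 and Lcn2, further members of lists, and the genes of contrasts averaged over lines or states.

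Alternatives were quantile normalization, centring each array on its median, an intensity trend with robust variances, only probe sets above the median level, 1 probe set per gene, only the groups of a contrast in the fit, a replicate block, array weights, a limit of 1.5-fold, the mean of all probe sets of a gene, and leaving out each array in turn. Adding 16 or 50 to every signal before taking log2 was chosen after the data were seen, to lower the weight of dim signals. The fit was tested on simulated arrays built from the real means and spreads with independent normal noise, and 200 of 22626 probe sets were changed in Z on. The changed probe sets were drawn only from those above the median level, so the recovery of changes in dimmer probe sets was not tested. In Z on against Z off it recovered 29% of the 100 changes of 1 on the log2 scale and 80% of the 100 changes of 2, with 3 false calls, and for the interaction 3% and 50%.

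Across arrays, Pearson correlations of log2 signals over the brighter 11313 probe sets lay between 0.944 and 0.976 within groups and between 0.924 and 0.973 across groups, so no pair of arrays looked like a repeated deposit. The beta-actin control signal for the 3′ end was 1273.2 on M on replicate 2 and between 2748.9 and 7541.8 on the others. No scan date or batch was used here.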

Results

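Liver RNA of 12 male mice, each 6 weeks old, was measured on 12 one-colour Affymetrix mouse arrays. The mice carried an inducible human alpha1-antitrypsin gene that was active in hepatocytes. Alpha1-antitrypsin is a secreted protease inhibitor made in large amounts by the liver, and its Z mutant folds poorly and is retained in the endoplasmic reticulum. M mice carried the wild-type form and Z mice the mutant form. The "off" groups received doxycycline at 40 µg/mL in drinking water from conception, which kept the transgene silent, and the "on" groups received none. Each of the 4 groups (M off, M on, Z off, Z on) held 3 arrays, which the labels call biological replicates. Every expressing mouse was also a mouse without doxycycline, and every Z mouse came from another transgenic line than the M mice, so the design does not separate expression from the absence of doxycycline, nor the Z form from its line. After scaling, the array medians lay between 38.8 and 47.2 signal units, and 22626 probe sets were tested. For arrays, the number of animals limits the precision.

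The human transgene had no probe set named for it in the annotation used, so its own transcript was not measured here. Probe sets for the mouse counterparts stood near the top of the scale in every group. Serpina1c read 22100 ± 2410 in Z on, 20200 ± 2850 in Z off, 19400 ± 1940 in M on and 22800 ± 1780 in M off (mean ± SD, n = 3 each). The corresponding signals of a first Serpina1b probe set were 15200 ± 1600, 15900 ± 2000, 16200 ± 4860 and 15300 ± 1890. Those of another were 15800 ± 1290, 14100 ± 1980, 13500 ± 380 and 13200 ± 3970, higher in Z on than in Z off. Alb, which encodes albumin, read 20600 ± 2980 in Z on and 19800 ± 2850 in Z off. Alb and the first Serpina1b probe set fell from replicate 1 to 3 in every group, so their SDs include that trend. None of these probe sets passed the test in a comparison of Z on with Z off. The log2 differences there were 0.13 for Serpina1c, -0.06 for the first Serpina1b probe set and 0.06 for Alb.

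The comparison of Z on with Z off asked how the liver responds to the mutant protein within 1 line. Alas2, the erythroid form of the first enzyme of heme synthesis, fell by 2.88 on the log2 scale, from 1280 ± 169 in Z off to 175 ± 37.2 in Z on (mean ± SD, n = 3 each; adjusted p = 0.00159). Both M groups read close to the lower value, 274 ± 28.3 in M off and 246 ± 12.8 in M on. Mndal, an interferon-inducible gene of the PYHIN family, rose from 2.00 ± 1.05 to 55.9 ± 39.5 (n = 3 each; log2 change 4.70, adjusted p = 0.0333). The Z off signal lay at the bottom of the scale, so the size is uncertain: the Mndal change ranged from 0.96 to 5.21 over the alternatives. Both M groups lay near 80 (81.3 ± 4.38 in M off and 77.6 ± 4.38 in M on). Another Mndal probe set read 4.10 ± 2.65 in Z off and 39.4 ± 10.1 in Z on and was not called. A probe set without a gene symbol, singled out after its values were seen, fell by 2.93 from a dim signal of 22.1 ± 3.44 to 2.93 ± 0.702. Alas2, the first Mndal probe set and the one without a symbol were the 3 calls at an adjusted p under 0.05 in limma, 1 higher and 2 lower. In each of them the 3 arrays of one group lay apart from the 3 of the other, as they did on 11.8% of all probe sets. The balance depended on the method: with an intensity trend and robust variances 8 passed, 6 of them higher. The beta-actin 3′ to 5′ ratio was 2.44 to 5.16 on the Z on arrays and 2.18 to 2.53 on the Z off arrays, and the 18S control signal for the 3′ end was at least 914.2 on the Z on and at most 373 on the Z off arrays. On the first principal component of the brighter probe sets (18.2% of their variance) the Z off arrays lay at 21.5 to 27.8 and no other array above 12.4. Alas2 passed without each of the 6 arrays in turn and lost its call when the fit held only the 2 Z groups (log2 change -2.88, adjusted p = 0.112). The Mndal call held in 2 of 6 such omissions and in 5 of 11 other settings.

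**Figure D1:**
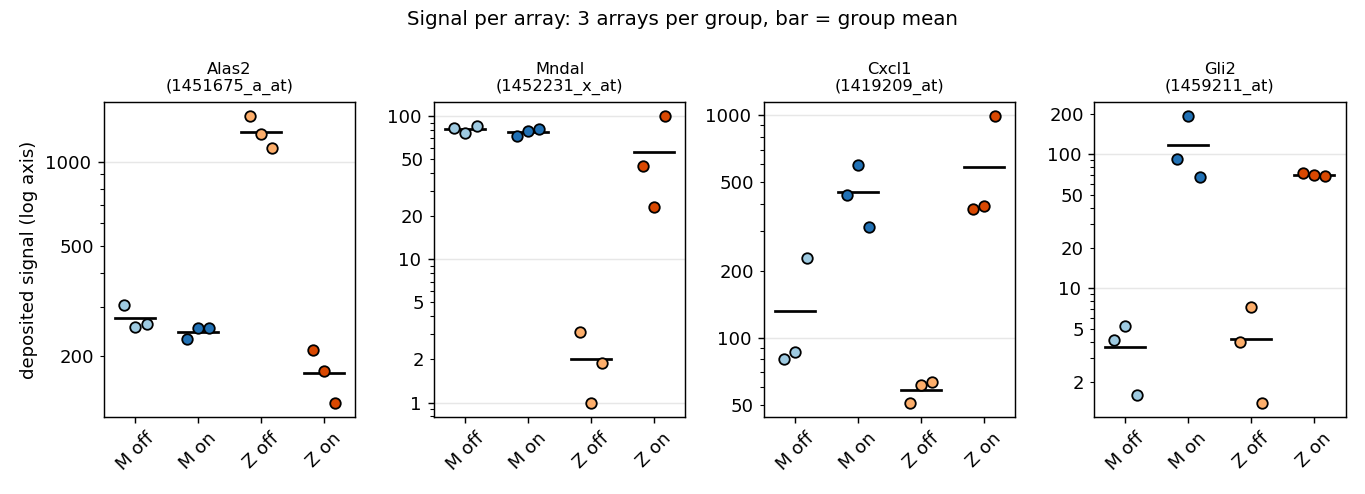
Deposited signal (log axis) of Alas2, Mndal, Cxcl1 and Gli2 on each of the 12 arrays by group; points are arrays and bars are group means. Alas2 averages 1280 in Z off and 175 to 274 in the other groups, and Cxcl1 averages 586 in Z on, 58.4 in Z off, 449 in M on and 131 in M off.

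Below the threshold, the smallest p-values among genes read higher in Z on belonged to Osbpl9, Mycl, Gli2 and Cxcl1. Cxcl1, a neutrophil-attracting chemokine, read 586 ± 349 in Z on and 58.4 ± 6.45 in Z off (n = 3 each; log2 difference 3.18, SE 0.48, adjusted p = 0.157). Adjusted over the list of NF-kappaB targets alone, Cxcl1 passed. A Gli2 probe set read 70.4 ± 2.34 in Z on and 4.20 ± 2.91 in Z off (adjusted p = 0.15). Among genes read lower, Osgin1, a gene induced by oxidative stress, read 437 ± 106 in Z on and 1570 ± 398 in Z off (adjusted p = 0.21), and Golph3l, Cul3 and Terf2ip had adjusted p-values of 0.126, 0.157 and 0.369.

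Stress genes named before the data were examined gave no call between Z on and Z off. Hspa5, the main chaperone of the endoplasmic reticulum, read 4380 ± 657 in Z on and 5230 ± 614 in Z off, a log2 difference of -0.26 (SE 0.19, adjusted p = 0.871). Ddit3, which encodes the stress transcription factor CHOP, read 85.9 ± 18.9 and 102 ± 17.5. The brightest Xbp1 probe set read 2060 ± 181 and 1970 ± 267, and the brightest Nfkbia probe set 1200 ± 112 and 1000 ± 120. The autophagy adaptor Sqstm1 read 1610 ± 187 and 2010 ± 147, with a log2 difference of -0.33 (SE 0.16, adjusted p = 0.804). The brightest Map1lc3b probe set read 1020 ± 108 and 820 ± 184, and Bcap31 read 1870 ± 219 and 1880 ± 260. Tgfb1 differed by -0.50 (SE 0.83) from a dim signal, and the brightest Ccnd1 probe set by -0.36 (SE 0.35). Rgs16, a regulator of G protein signalling, was dim and its 3 probe sets disagreed, with log2 differences of -0.22, 2.07 and 3.69 and adjusted p-values of 0.973, 0.799 and 0.694. On the last of these the Z on arrays read 59.4, 77.8 and 2.3.

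As a list, the ER chaperones and ER-associated degradation genes shifted down in Z on (adjusted p = 0.0292 with the preset correlation, adjusted p = 0.82 with an estimated correlation), with 7 of 24 members higher and 17 lower. Adjusted over the list alone, 2 members passed and both were lower. These were Syvn1, a ubiquitin ligase of ER-associated degradation (log2 change -0.90), and Creld2 (-1.15), and over all probe sets no member passed. The list lost its call without Z off replicate 2 or 3 (adjusted p = 0.0913 and 0.158) and without Z on replicate 1 or 2 (0.368 and 0.209). The integrated stress response (adjusted p = 0.827), NF-kappaB targets (adjusted p = 0.827), autophagy and lysosome genes (adjusted p = 0.526), regulators of G protein signalling (adjusted p = 0.958) and apoptosis genes (adjusted p = 0.82) did not pass. Camera tests for a shift to one side. In fry's mixed test, NF-kappaB targets (adjusted p = 1.21e-04) and autophagy and lysosome genes (0.025) passed. The integrated stress response (0.209) and regulators of G protein signalling (0.581) did not pass in it. Adjusted over their lists alone, 1 NF-kappaB target (Cxcl1, log2 change 3.18) was higher and 1 regulator of G protein signalling was lower.

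Genes of extracellular matrix and stellate cell activation shifted down in Z on (adjusted p = 0.00284, adjusted p = 0.34 with an estimated correlation), with 21 of 24 members lower and a median log2 difference of -0.45. Col3a1, a fibrillar collagen, differed by -1.14 (SE 0.30), Sparc by -0.57 and Mmp14 by -0.55, while Ccn2 differed by 0.79, and no member passed adjusted over the list alone or over all probe sets. Stellate cell markers, which share 3 members with that list, shifted down as well, with 8 of 9 lower (adjusted p = 0.0234, adjusted p = 0.34 with an estimated correlation). The stellate cell call was lost without Z off replicate 1 or 3 (adjusted p = 0.0684 and 0.0701) or Z on replicate 1 (0.086) and with the mean of all probe sets of a gene (0.0598).

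Of the metabolic lists, cholesterol synthesis and gluconeogenesis passed. Fatty acid synthesis and storage did not (adjusted p = 0.61 with the preset correlation), though 1 of its members was higher adjusted over the list alone. Cholesterol synthesis genes shifted up in Z on, with 13 of 16 members higher and a median log2 difference of 0.46 (adjusted p = 0.00284, adjusted p = 0.82 with an estimated correlation). That list did not pass without Z on replicate 3 (adjusted p = 0.33) or with the mean of all probe sets of a gene (adjusted p = 0.0598). Msmo1, Fdft1 and Cyp51, enzymes of the sterol pathway, differed by 0.73, 0.71 and 0.59, and no member passed adjusted over the list alone. Gluconeogenesis genes shifted up with 9 of 13 higher (adjusted p = 0.0471, adjusted p = 0.34 with an estimated correlation), and Pck1, the rate-limiting enzyme of gluconeogenesis, passed adjusted over the list alone (log2 change 1.61). The gluconeogenesis call was lost under each omission of 1 array, with adjusted p-values from 0.0554 to 0.123, and also with the mean of all probe sets of a gene (adjusted p = 0.102) and with a replicate block (adjusted p = 0.081).

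Circadian clock genes shifted up in Z on (adjusted p = 0.00284, adjusted p = 0.34 with an estimated correlation), with 11 of 18 members higher. Adjusted over the list alone, 7 members rose and 1 fell; over all probe sets none passed. The clock output Dbp rose by 3.39, Nr1d2 by 1.59 and Per1 by 1.57 on the log2 scale, and Arntl, which encodes BMAL1, fell by 2.70. Dbp read 107.1, 51.1 and 23.8 on the Z off arrays and 1365, 1385.3 and 80.1 on the Z on arrays, so that Z on replicate 3 lay with Z off. The M groups read 949 ± 138 (off) and 1320 ± 231 (on). The clock list did not pass without Z on replicate 2 (adjusted p = 0.0503). For erythroid markers the test pointed down and the median log2 difference was 0.06 (adjusted p = 0.411). The other lists, 29 in all, had adjusted p-values from 0.0612 to 0.958.

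**Figure D2:**
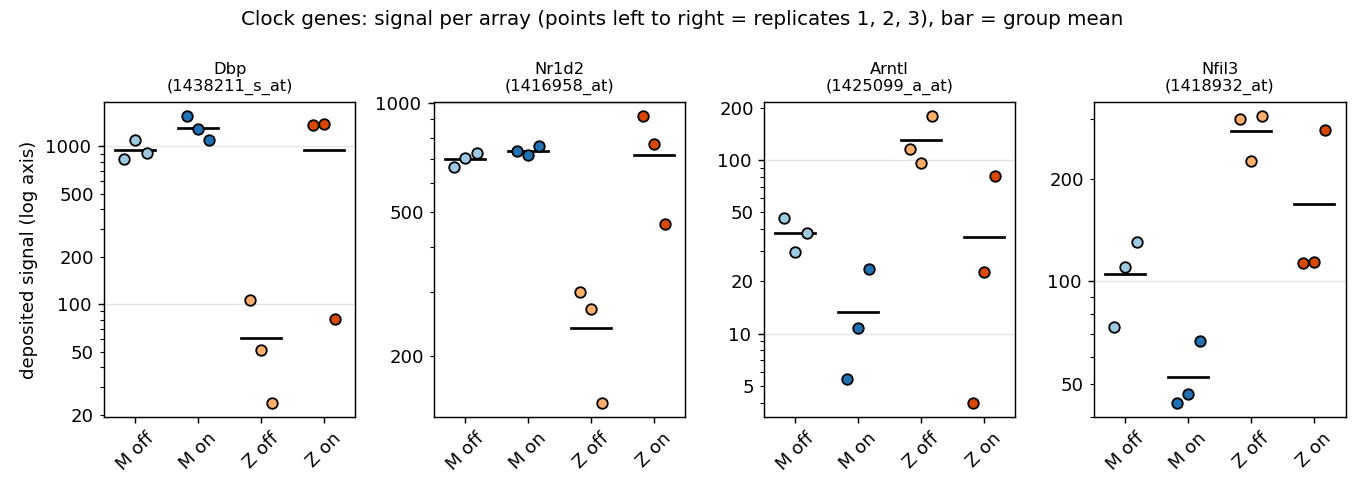
Deposited signal (log axis) of Dbp, Nr1d2, Arntl and Nfil3 on each array by group; points from left to right are replicates 1, 2 and 3 and bars are group means. Dbp averages 60.7 in Z off against 949 in M off, Arntl and Nfil3 lie higher in Z off than in M off, and Z on replicate 3 reads 80.1 for Dbp.

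The comparison of M on with M off asked the same of the wild-type protein. Its smallest adjusted p-values among the lists, with the preset correlation, were those of lipid synthesis. Cholesterol synthesis genes shifted up with 15 of 16 members higher and a median log2 change of 0.80 (adjusted p = 1.81e-12, adjusted p = 0.22 with an estimated correlation). Adjusted over the list alone 9 members rose, among them Sqle (1.21), Fdps (1.17), Msmo1 (1.16) and Hmgcs1 (1.11), all enzymes between acetyl-CoA and cholesterol. Fatty acid synthesis and storage genes shifted up with 19 of 21 members higher and a median of 0.59 (adjusted p = 1.57e-09, adjusted p = 0.22 with an estimated correlation). Fasn, which encodes fatty acid synthase, rose by 1.37 and Elovl6 by 1.21 when adjusted over the list alone. Fasn read 2240 ± 309 in M on and 863 ± 29.9 in M off (n = 3 each), and over all probe sets it did not pass (adjusted p = 0.201). Both lists passed without each of the 6 arrays in turn.

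A further 4 lists passed in M mice. Male-biased liver genes shifted down with 9 of 11 lower (adjusted p = 0.00533, adjusted p = 0.28 with an estimated correlation), where Cyp7b1 differed by -0.83 and the complement gene C6 by -0.63. Matrix and stellate activation genes shifted down with 19 of 24 lower (adjusted p = 0.00632, adjusted p = 0.28 with an estimated correlation), where Dcn differed by -1.01, Ccn2 by -0.81 and Acta2 by -0.76. Stellate cell markers (7 of 9 lower, adjusted p = 0.0664) and sinusoidal endothelial markers (9 of 11 lower, adjusted p = 0.0752) did not pass. Cell cycle genes shifted up with 20 of 25 higher (adjusted p = 0.0138, adjusted p = 0.51 with an estimated correlation), where Mcm5 differed by 1.59 and Ccnd1 by 1.01. No single member of the male-biased, matrix or cell cycle lists passed, adjusted over its list alone or over all probe sets. Skeletal muscle markers shifted down with 6 of 9 lower (adjusted p = 0.0309, adjusted p = 0.44 with an estimated correlation). Their mean signal was 41.0 and 66.7 on M off replicates 1 and 3 and between 8.29 and 19.8 on the other 10 arrays. Each of these 4 calls was lost under some omissions of 1 array. Male-biased genes were lost without M off replicate 2 or M on replicate 2 (adjusted p = 0.0522 and 0.0884), and matrix genes without M off replicate 3 or M on replicate 2 (0.0523 and 0.0709) or with the mean of all probe sets of a gene (0.0591). Cell cycle genes were lost without M off replicate 2 or 3 or M on replicate 3 (0.107, 0.063 and 0.676), and muscle markers without M off replicate 1 or 3 or M on replicate 2 or 3 (0.109, 0.314, 0.0547 and 0.0958). The other 29 lists had adjusted p-values from 0.0664 to 0.966.

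No probe set passed in M on against M off in limma, where 1172 of 22626 (5.18%) had an unadjusted p under 0.05 and the smallest adjusted p was 0.0724. With an intensity trend and robust variances in limma, 8 passed. The smallest p-values among genes read higher belonged to Nfkbie, Gli2, Mmd2, Scel and Fasn. Nfkbie, an inhibitor of NF-kappaB, was dim at 27.0 ± 6.13 in M on and 3.53 ± 1.47 in M off. Gli2 read 117 ± 66.1 and 3.63 ± 1.84 (log2 difference 5.03, adjusted p = 0.0899), an uncertain size against a signal at the bottom of the scale, and another Gli2 probe set differed by 3.03 (adjusted p = 0.782). Mmd2 read 202 ± 33.3 and 37.3 ± 3.18 (adjusted p = 0.136). Among genes read lower, Apobec2, Msi2, Peg12, Cntn4 and Icam5 had the smallest p-values, with adjusted values of 0.0796, 0.102, 0.189, 0.225 and 0.225. Adjusted over their lists alone, Igfbp1, an insulin-repressed growth factor binding protein, fell by 3.15, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.83, and the NF-kappaB targets moved both ways, with Nfkbie (2.99) and Cxcl1 (1.90) higher and Ccl5 (-2.45) and Nfkbia (-0.61) lower. Of the stress genes fixed in advance, Ddit3 read 116 ± 28.1 in M on and 64.4 ± 19.1 in M off (log2 difference 0.86, SE 0.28), and Hspa5 differed by -0.04 (SE 0.19).

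**Figure D3:**
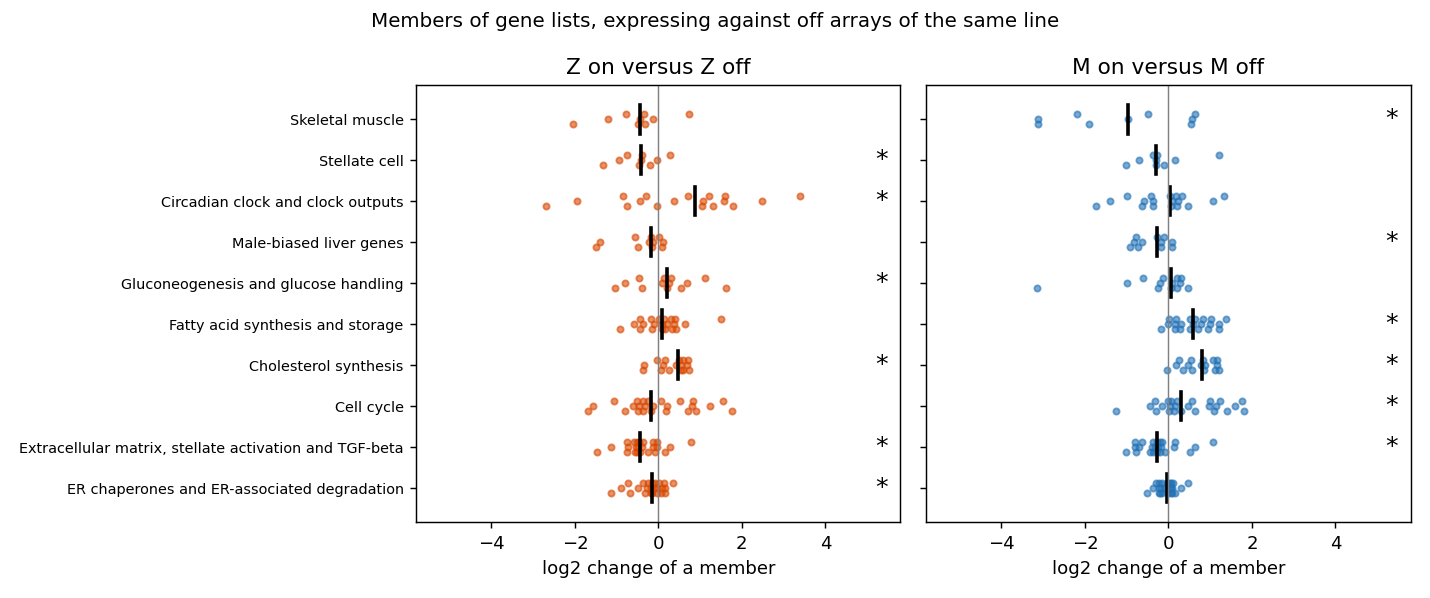
Log2 change of each member of the 10 gene lists that passed in Z on versus Z off or in M on versus M off; points are genes, black bars are list medians and an asterisk marks an adjusted p under 0.05 with the preset correlation. The cholesterol synthesis medians are 0.46 in Z mice and 0.80 in M mice, and the circadian clock list is spread to both sides in Z mice.

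The interaction asked whether the change on expression differed between Z and M mice, with any effect of doxycycline common to both lines removed. The lists of lipid synthesis had smaller median changes in Z mice than in M mice. Fatty acid synthesis and storage genes had 16 of 21 members lower (adjusted p = 0.00479, adjusted p = 0.73 with an estimated correlation), among them Fasn (-1.21), Pklr (-1.13) and the lipid droplet gene Plin2 (-0.89). Cholesterol synthesis genes had 14 of 16 lower (adjusted p = 0.0198, adjusted p = 0.73 with an estimated correlation), and their median was already higher by 0.64 in Z off than in M off. Clock genes (12 of 18 higher, adjusted p = 0.00514), gluconeogenesis genes (10 of 13 higher, adjusted p = 0.041), acute phase genes (18 of 26 higher, adjusted p = 0.041) and PPAR-alpha targets (15 of 20 higher, adjusted p = 0.0479) shifted the other way. Their adjusted p-values with an estimated correlation were 0.67, 0.67, 0.74 and 0.73. The lists of clock genes and PPAR-alpha targets were already lower in Z off than in M off. Adjusted over the lists alone, Cry2 (2.70), Per1 (2.19), Nr1d2 (1.51) and Cyp4a14 (4.12), a fatty acid omega-hydroxylase, passed. Cyp4a14 was dim, at 1.90 ± 0.529 in Z off and 21.5 to 40.6 on average in the other groups, so the size of its difference is uncertain. Of the 6 lists, the clock genes passed without each of the 12 arrays in turn, and fatty acid synthesis was lost without Z on replicate 3 (adjusted p = 0.075). Cholesterol synthesis was lost in 6 of 12 omissions (highest adjusted p = 0.323 without Z on replicate 2), gluconeogenesis in 8 (0.177 without M on replicate 2) and PPAR-alpha targets in 9 (0.323 without Z on replicate 2). These 3 lists were also lost with the mean of all probe sets of a gene (adjusted p = 0.089 each), and PPAR-alpha targets with 16 added to every signal (adjusted p = 0.0506). Acute phase genes were lost in 7, most clearly without Z on replicate 3 (adjusted p = 0.788), which alone read 6737.2 for Saa1 and 4508.4 for Saa2, against 441.9 to 532 and 91.5 to 100.4 on the other Z on arrays. The remaining 29 lists had adjusted p-values from 0.113 to 0.931.

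No probe set passed for the interaction in limma, where 1172 (5.18%) had an unadjusted p under 0.05. With an intensity trend and robust variances in limma, 2 passed. Alas2 came nearest (log2 difference of changes -2.73, SE 0.28, adjusted p = 0.0624) and passed under 9 of the alternatives tried. No probe set passed after quantile normalization or with a replicate block. Among omissions of 1 array, any probe set passed only without M on replicate 3 or Z on replicate 1. Scel (-5.07, adjusted p = 0.0708), Gbx2, Nfkbie and Cd4 followed among the negative values, and Mndal (4.77, adjusted p = 0.23), Cntn4, Stbd1, Msi2 and Xiap among the positive ones.

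Z on against M on compared livers that expressed either form. Asic5, an ion channel gene, read 51.5 ± 4.35 in Z on and 306 ± 29.8 in M on (n = 3 each) and was lower by a log2 change of -2.57 (adjusted p = 0.00806), and the probe set without a gene symbol that was called in Z on against Z off was lower by -3.03 (adjusted p = 0.0351). These were the 2 calls, both lower, with 3 of 3 arrays apart, as on 12.1% of all probe sets. Neither was called when M on replicate 1 was left out, with a replicate block or with only these groups in the fit. The direction of the calls depended on the setting, with 9 calls (6 higher) after quantile normalization and 22 (13 higher) with an intensity trend and robust variances. Just above the threshold lay Acaa2 (1.51), Apobec2 (2.42), Msi2 (2.66), Xiap (3.44) and Rps9 (3.18) among genes read higher, with adjusted p-values from 0.0618 to 0.0759. Terf2ip (-3.23), Nudt2 (-1.12), Aldh1b1 (-1.70) and Mccc1 (-1.23) were read lower, with adjusted p-values from 0.0759 to 0.091.

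Male-biased liver genes shifted up in Z on against M on with 9 of 11 members higher (adjusted p = 1.29e-04, adjusted p = 0.34 with an estimated correlation). Adjusted over the list alone, Cyp7b1, an oxysterol hydroxylase, rose by 1.74 and C6 by 1.02. Fatty acid synthesis genes shifted down with 20 of 21 members lower (adjusted p = 0.00194, adjusted p = 0.37 with an estimated correlation), with Elovl6 at -0.88 and Fasn at -0.71. Cell cycle genes shifted down with 19 of 25 lower (adjusted p = 0.0106, adjusted p = 0.42 with an estimated correlation), with Mcm3 at -1.60 and Cdc20 at -1.38. Adjusted over their own lists, the acute phase gene Saa3 (1.71) and the insulin-sensitising serpin Serpina12 (2.03) were higher and Cyp2c55 was lower (-2.63). The fatty acid call was lost without Z on replicate 3 or M on replicate 1 (adjusted p = 0.123 and 0.0755), and the cell cycle call without Z on replicate 1 or M on replicate 3 (0.0724 and 0.367). The other 32 lists had adjusted p-values from 0.0736 to 0.942.

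Z off against M off compared the lines with neither protein expressed, and it gave the largest number of calls, 16 probe sets of 14 named genes and 1 without a symbol, 10 higher and 6 lower in Z off. That balance depended on the method, with 13 of 33 higher among probe sets above the median level and 14 of 36 higher with 50 added to every signal. Asic5 was lower by a log2 change of -3.40 (46.2 ± 12.4 against 479 ± 51.3, n = 3 each; adjusted p = 5.94e-04). Mndal was lower by -5.49 on 1 probe set and -4.21 on another, with Z off signals of 2.00 and 4.10 at the bottom of the scale, so the sizes are uncertain. On the first of these the difference ranged from -5.88 to -1.34 over the alternatives, and the call held in 4 of 6 omissions of 1 array. Alas2 was higher by 2.22 (adjusted p = 0.00832). Enzyme genes on both sides included Cyp3a13 (-1.77), Aldh1b1 (-1.83), Mccc1 (-1.41), Isoc2b (2.07) and the fatty acid oxidation gene Acaa2 (1.58). Gbx2 (4.04), Nfkbie (2.76) and Lfng (1.86) were higher from dim signals. Over the alternatives their lowest changes were 0.31, 0.445 and 0.57, so these sizes are uncertain too. Rps9 (3.48), Uri1 (1.95) and Vps37c (1.62) were higher as well. With the mean of all probe sets of a gene, which brings in probe sets that did not follow, Rps9 differed by 0.66 (adjusted p = 0.541) and Uri1 by 0.50 (adjusted p = 0.599). Acaa2 differed by 0.59 in that setting, and its highest adjusted p in limma over the alternatives was 0.391. All 3 Z off arrays lay on the same side of the 3 M off arrays for each of these genes, which the naming rule required. The same held for 15.1% of all probe sets. Control signals differed between these groups too: the 3′ to 5′ ratio of beta-actin was 2.18 to 2.53 on the Z off arrays and 2.72 to 3.89 on the M off arrays. The 18S signal for the 3′ end was 93.9 to 373 and 568.2 to 709.8. The Gapdh ratio averaged 1.26 and 1.52, but its ranges overlapped (1.087 to 1.49 and 1.481 to 1.541). The number of calls fell to between 1 and 6 when 1 array was left out. Asic5 passed in all 6 omissions, Alas2 in 5, and Nfkbie and Rps9 in 1. Acaa2, Aldh1b1, Cyp3a13, Gbx2, Isoc2b, Lfng, Mccc1, Uri1 and Vps37c passed in 0 of 6, and with only these groups in the limma fit 0 of the 16 calls remained (1749 at an unadjusted p under 0.05 in the fit of all groups).

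Of the 15 called probe sets with a gene symbol, 3 had a bright probe set of the same gene beside them (mean signal above 100). None of these bright probe sets shared the difference, and the other called probe sets could not be checked in this way. The called Acaa2 probe set read 5350 ± 158 in Z off and 1800 ± 75.8 in M off (mean ± SD, n = 3 each), while the brightest other one read 2280 ± 138 and 2180 ± 46.9. For Rps9 the called probe set read 419 ± 78.1 and 42.7 ± 23.1, while the brighter one read 1360 ± 60.4 and 1760 ± 99.6. For Uri1 the called probe set read 261 ± 37.3 and 68.4 ± 14.9, while the brightest other one read 280 ± 24.5 and 340 ± 37.5. The expressing groups, which share no array with these, differed on the called probe sets by 1.51 (Acaa2), 3.18 (Rps9) and 1.83 (Uri1) on the log2 scale.

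**Figure D4:**
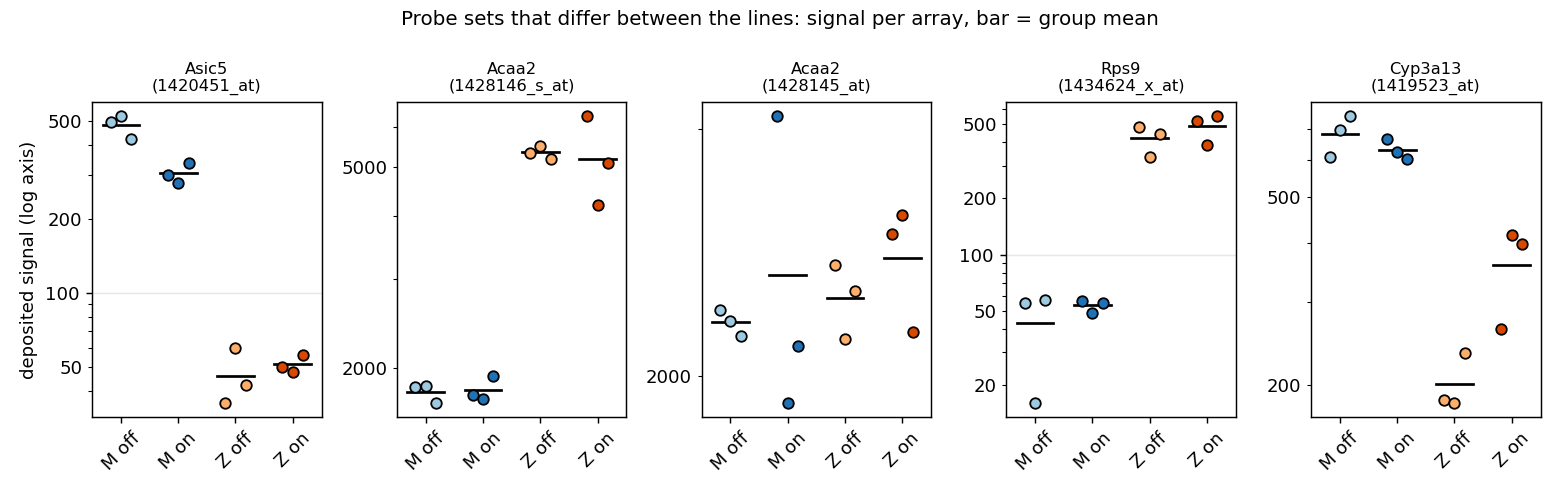
Deposited signal (log axis) of Asic5, of 2 probe sets of Acaa2, of Rps9 and of Cyp3a13 on each array by group; points are arrays and bars are group means. The called probe set of Acaa2 averages 5350 in Z off and 1800 in M off, while the other averages 2280 and 2180.

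Among the gene lists, cholesterol synthesis shifted up in Z off against M off with 15 of 16 members higher (adjusted p = 3.98e-07, adjusted p = 0.35 with an estimated correlation), where Fdps (1.22), Pmvk (1.18) and Idi1 (0.89) passed adjusted over the list alone. Male-biased genes shifted up with 9 of 11 higher (adjusted p = 9.46e-04, adjusted p = 0.35 with an estimated correlation), and Elovl3 (2.07), Cyp7b1 (1.04) and Slco1a1 (0.75) passed over the list alone. PPAR-alpha targets shifted down with 16 of 20 lower (adjusted p = 0.00217, adjusted p = 0.35 with an estimated correlation), with the dim Cyp4a14 at -4.28 (mean signal 1.90 in Z off and 40.6 in M off) and the fatty acid transporter Cd36 at -1.48. Clock genes shifted down with 12 of 18 lower (adjusted p = 0.0065, adjusted p = 0.35 with an estimated correlation), and 9 fell and 2 rose adjusted over the list alone, led by Nr1d2 (-1.61) and Dbp (-4.22). The other 31 lists had adjusted p-values from 0.0598 to 0.936. In bile acid synthesis and transport, 5 members rose adjusted over the list alone, among them the synthesis enzymes Cyp8b1 (1.64), Cyp7a1 (1.22) and Cyp27a1 (0.60), while the list itself did not pass (adjusted p = 0.297). In autophagy and lysosome genes, Sqstm1 (0.59) was higher and Ctsl (-0.87) and Bnip3 (-0.82) were lower adjusted over the list alone.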

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

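The tests of clock genes below were chosen only after the result was seen, while the splits of the arrays were planned.

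For 6 gene lists the change on expression differed between Z and M mice with the preset correlation, by limma's test of the difference itself. Among them, cholesterol synthesis genes were already higher, and clock genes and PPAR-alpha targets already lower, in Z off than in M off. For these lists a difference in the off arrays could not be told apart from a different response. Their adjusted p-values were 0.00479 for fatty acid synthesis and storage, 0.00514 for clock genes, 0.0198 for cholesterol synthesis, 0.041 for gluconeogenesis, 0.041 for acute phase genes and 0.0479 for PPAR-alpha targets. With an estimated correlation none of the 6 passed, the lowest adjusted p being 0.67. In 13 of 100 splits drawn from the arrays within each line, the real one included, as many lists passed. The highest of the other splits gave 10 lists against 6 in the real one, so a random grouping was not excluded for this count. No probe set passed for the interaction in limma (1172 at an unadjusted p under 0.05). A count of 0 is reached by all 100 splits by construction, so the splits say nothing about it; the highest other gave 3. Among these lists, only the clock genes passed without each of the 12 arrays in turn.

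In the clock list, the Z off arrays stood apart. Against M off, the genes that peak with Dbp were lower by a mean log2 difference of -1.41 (SE 0.20, n = 3 each) and those that peak with Arntl were higher by 1.32 (SE 0.14). A shift of whole arrays by the scaling would move both sets the same way, and the value of 1.32 argues against it. The difference between the sets was -2.73 (SE 0.32) between lines in which neither protein was expressed, which argues against a response to the expressed Z protein as its source. Another time of day or feeding phase at collection is a candidate explanation, as a hypothesis, since both sets moved as it requires; on Z on replicate 3 the same difference was -2.44, against 1.24 and 0.44 on the other Z on arrays. It was 0.90, 1.48 and 0.58 on the M on arrays against -0.19, 0.18 and 0.01 on the M off arrays, so it was also higher on every M on array. Between Z on and M on it differed by -1.24 (SE 1.15), a value too uncertain to show that the lines differ when the proteins are expressed. No collection time was used here, and a clock difference between the lines stays open and untested.

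Control probe sets for 18S ribosomal RNA, which no comparison used, gave a higher signal in Z on than in Z off. The ratios of group means were 6.21 for the 3′ end, 6.59 for the middle and 11.6 for the 5′ end (n = 3 each). The 3′ means were 1300 in Z on, 209 in Z off, 442 in M on and 621 in M off.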

How the results depend on the processing

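The offsets of 16 and 50 were chosen only after the data were seen; the other alternatives were planned. Where a count moved, the cause was not tested.

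In Z on against Z off, 3 probe sets passed (1 higher). The count was 8 (6 higher) with an intensity trend and robust variances, 1 with arrays centred on their medians, 1 with only probe sets above the median level, 1 with 16 added, 1 with 50 added and 0 with only the Z groups in the fit, which leaves fewer degrees of freedom. In M on against M off, 0 passed in limma (1172 at an unadjusted p under 0.05). The count was 2 after quantile normalization, 5 with centred arrays, 8 with trend and robust variances, 2 above the median level, 1 with 1 probe set per gene, 1 with array weights, 3 with 16 added and 5 with 50 added. For the interaction, 0 passed in limma (1172 at an unadjusted p under 0.05). The count was 1 with centred arrays, 2 with trend and robust variances, 1 above the median level, 2 with 1 probe set per gene, 1 with array weights, 1 with 16 added and 2 with 50 added. That contrast uses all groups, so a fit of its own groups alone was not run.

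In Z on against M on, 2 passed (0 higher). The count was 9 (6 higher) after quantile normalization, 22 (13 higher) with trend and robust variances, 20 (12 higher) above the median level, 10 (5 higher) with 16 added, 19 (11 higher) with 50 added and 0 with only these groups in the fit. In Z off against M off, 16 passed (10 higher). The count was 51 (26 higher) with trend and robust variances, 33 (13 higher) above the median level, 26 (13 higher) with array weights, 36 (14 higher) with 50 added and 0 with only these groups in the fit. Quantile normalization gave 17 calls there, 15 of them the same. A limit of 1.5-fold changed none of the 5 counts.

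Same-numbered arrays of different groups were not treated as pairs in the main fit. Their 18 pairs had correlations from -0.0826 to 0.161, against -0.183 to 0.157 for other numbers. For 6 of 12 arrays the best partner in another group had the same number. In each group the percentage of signal in the 10 brightest probe sets fell from replicate 1 (3.94 to 4.92) to 2 (3.26 to 3.85) and 3 (3.16 to 3.29). The share of signal in the brightest probe sets thus followed the replicate number in all 4 groups. Alb also fell in this order in each group, for example 26306, 21359.3 and 16710.8 in M off. Serpina1c did not in M on (21554.9, 17739.5 and 19025.5). The main fit did not model this trend. With a replicate block, 1 probe set passed in Z on against Z off, 0 in Z on against M on and 6 (3 higher) in Z off against M off.

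Leaving out 1 array at a time gave 2 to 5 probe sets in Z on against Z off, 0 to 2 in M on against M off, 0 to 2 for the interaction, 0 to 5 in Z on against M on and 1 to 6 in Z off against M off. In Z on against M on, 0 came without M on replicate 1, and in Z off against M off, 1 came without M off replicate 3. For gene lists the ranges were 3 to 5 (of 6), 4 to 8 (of 6), 2 to 8 (of 6), 2 to 5 (of 3) and 4 to 7 (of 4). An estimated correlation left 0 lists in each of the 5 contrasts, and fry 0, 0, 0, 1 and 0. Fry's mixed test, which counts changes in either direction, called 13, 11, 3, 8 and 15. With the mean of all probe sets of a gene, 3 lists passed for the interaction, 5 in Z on against M on and 7 in Z off against M off.

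The alternatives were followed for each called list and for 17 of the 21 calls of probe sets, not for those without a gene symbol or for the dimmer Mndal probe set, and none of these reversed. The 17 kept their call in 181 values and lost it in 118, and called lists in 192 and 119. Of the values of named probe sets without a call, 4965 stayed as they were, 143 changed sign and 82 passed the threshold. Signals near the background limit the size of changes in dim genes. The Mndal change between Z on and Z off ranged from 0.96 to 5.21 over the alternatives (adjusted p from 0.00217 to 0.348), and that of Alas2 from -3.03 to -2.57 (adjusted p from 3.44e-07 to 0.112).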

Other observations

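The tests of Alas2 and of probe sets of 1 gene were chosen only after the result was seen, while the splits of the arrays were planned.

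Alas2 was high on the Z off arrays alone. Blood or erythroid cells in those samples would also bring globin transcripts, but the highest change among 4 bright globin probe sets was -0.24 (SE 0.22) in Z off against M off. The reading of that test was settled after the values were known. Its bound was a rise by a fixed share of the Alas2 change (2.22). By its spread alone, 1 of the 4 (log2 difference -0.54, SE 0.96) did not rule out a rise to that bound, and the other 3 did. Dimmer erythroid markers went both ways, with Hba-a1 (2.18, SE 1.10), Epb42 (0.91), Hemgn (0.89) and Car2 (0.34) higher and Slc4a1 (-0.53), Klf1 (-0.31), Car1 (-0.18) and Ermap (-0.15) lower, and the erythroid list had a median of 0.34 (adjusted p = 0.238). The bright globin values argue against such cells as the whole source of the Alas2 difference only. A shift by the scaling is argued against by the change of -2.88 in Z on against Z off after quantile normalization. A line difference together with a response to the Z protein is a hypothesis that stays open and was not tested. It is not the only one, since the Z off arrays also stood apart on the first principal component (21.5 to 27.8, no other array above 12.4). Another property of the Z off samples could not be told apart from it.

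Probe sets of Acaa2, Uri1 and Rps9 differed between the lines while bright probe sets of the same genes did not follow. They were the only 3 of 15 called probe sets with a gene symbol that had such a bright sibling. The highest change of such a sibling in the direction of the call was 0.15, which argues against a change of the whole transcript. The changes in expressing and off groups, which share no array, lay at most 0.502 standard errors apart. A line difference under the probes, such as a sequence variant or another transcript end, is therefore a candidate explanation, as a hypothesis. These 2 kinds were not separated from each other, nor from other sources of signal on these probe sets. Of the 16 calls in Z off against M off, 12 had the same sign in Z on against M on and 9 also had an unadjusted p under 0.05 there.

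The other splits of 6 arrays number 10 with the real one, too few for a share under 0.05. In Z on against Z off, 1 of the 10 splits gave as many probe sets (3 in the real one, 1 in the highest other) and 1 as many lists (6 and 5). In M on against M off the real count of probe sets was 0 (highest other 4), which all 10 of the 10 reach by construction, so they say nothing about it; 1 gave as many lists (6 and 5). In Z on against M on, 1 gave as many probe sets (2 and 1) and 8 as many lists (3 and 8). In Z off against M off, 1 gave as many probe sets (16 and 1) and 1 as many lists (4 and 2).

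Averaged over both lines, 2 probe sets passed between on and off: Alas2 (log2 change -1.52) and Gli2 (4.70), each with an adjusted p of 0.0158, and Cxcl1 did not (2.54, adjusted p = 0.143). The Alas2 average joins -2.88 in Z mice with -0.16 in M mice, so it is not a change shared by the lines. Gli2 was measured against off signals of 3.63 and 4.20, at the bottom of the scale, and its other probe set differed by 1.84 in Z mice and 3.03 in M mice (adjusted p = 0.823 and 0.782). Averaged over both states, 20 passed between Z and M, 10 higher and 10 lower, led by Asic5 (-2.99, adjusted p = 7.69e-05). Hc, which encodes complement C5, was among those higher (1.20, adjusted p = 0.0223) and read 3270 ± 667 in Z off, 2250 ± 198 in Z on, 1150 ± 217 in M off and 1200 ± 62.2 in M on. These averages and genes were chosen after the values were seen. Z on replicate 3 read 761.2 for the neutrophil and acute phase gene Lcn2, against 13.7 and 4.1 on the other Z on arrays.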
